A study of Mus musculus with 12 samples.

How the data were processed

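RNA of 12 samples was measured on single-color arrays with 22690 probe sets per array. Per the labels, 3 samples were lactating glands of NMRI mice, 3 lactating glands of WAP-SVT/t mice, 3 WAP-SVT/t tumors and 3 the cell lines ME-A, ME-B and ME-B-T/t. The deposited values are probe set signals in intensity units on a linear scale, which the authors made with MAS5, per the labels. The MAS5 version, background method, detection calls and scaling target are not given in the sources used here. The deposited signals were near a common scale: means without the lowest and highest 2% of probe sets lay within 1.19-fold of each other. Only the table of signals was used. The raw scans were not analysed here.

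Each array was scaled to the mean of these trimmed means over the 12 arrays. Signals under the pooled 30th percentile, 57.4, were set to that floor, and log2 values were taken. All 64 Affymetrix control probe sets were left out. Probe sets were joined to genes by the platform's table and current mouse symbols: 20380 named 1 gene, 691 several genes and 1555 none, and the latter groups were left out. Of 12393 genes, 4956 had several probe sets. The probe set with the highest mean log2 signal over the arrays of a fit stood for its gene, and was kept if at least 3 arrays lay above the pooled median of 139.9. Where the lines were compared with each other, 1 line above that median was enough. Tested on their own, probe sets of the same gene were called in opposite directions in 5 genes for transgenic against NMRI glands, 0 for tumors against transgenic glands, 8 for tumors against NMRI glands and 0 for lines against tumors. Folds are computed from values at or above the floor. Where every array of 1 group was at the floor, a fold is given as at least that size, and where some were, the fold depends on the floor.

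Precision is limited by the number of arrays. Between 67.7% and 72.6% of probe sets lay above the floor on each array. Ratios of 3-prime to 5-prime control signals of Gapdh were computed as a measure of RNA integrity.

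Genes were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend and Benjamini-Hochberg adjustment over all genes tested. A gene passed at an adjusted p under 0.05. The 9 tissue arrays were fitted together as 3 groups, with 6 residual degrees of freedom, and gave 3 comparisons. Lines and tumors were fitted as 2 classes of 3 arrays, with 4 residual degrees of freedom. All tests were two-sided. ME-B was compared with ME-A and ME-B-T/t with no test: a gene counted when it differed from both by 4-fold or more in the same direction. The medians of gene lists there were ranked among 10000 random lists of equal size, matched on mean expression in 10 bins. The overlap of calls against NMRI glands was set against independent lists and the correlation of the differences over genes was set against 100 simulations of unchanged groups that share the controls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

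The 29 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The lists were milk proteins and secretory differentiation, fatty acid and triglyceride synthesis, cholesterol synthesis, G1/S and DNA replication, G2/M and chromosome segregation, DNA repair and damage checkpoint, p53 target genes, the RB and cyclin-dependent kinase pathway, apoptosis regulators, interferon response, antigen presentation, involution and acute phase, imprinted growth genes, glycolysis and hypoxia response, oxidative phosphorylation, ribosomal proteins, the unfolded protein response and secretion, and epithelial-mesenchymal regulators. Marker lists covered T and NK cells, B and plasma cells, macrophages and myeloid cells, adipocytes, fibroblasts and matrix, endothelium, luminal epithelium, basal and myoepithelial cells, skeletal muscle, erythroid cells, and skin and hair follicle. Of 943 list genes, 830 had a probe set. Some genes were in several lists, so the lists are not independent. Rbl1, E2f1, Ccne1 and Ccne2 were in the G1/S and RB lists, and Cdkn1a in the p53 and RB lists. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Erythroid markers had too few tested genes in every comparison, and T and NK cell and skin markers had too few in lines against tumors. With the preset correlation 16, 17, 17 and 8 lists passed in the 4 comparisons, in the order transgenic against NMRI glands, tumors against transgenic glands, tumors against NMRI glands and lines against tumors. With the estimated correlation 3, 0, 3 and 1 passed, and 6, 5, 6 and 1 had an unadjusted p under 0.05.

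Named genes were, for each replicated comparison, the 6 with the largest rise and the 6 with the largest fall among called genes without overlap between groups. Added to these were the 3 members with the smallest p of each list that passed or had at least 3 called members, and always Wap, Trp53, Rb1, Cdkn2a, Mki67 and Krt18 where measured. For ME-B they were the 8 genes highest and the 8 lowest against both other lines.

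The labels number the glands but do not say whether equal numbers were handled together. Across genes, which are not independent replicates, deviations of equally numbered transgenic and NMRI glands from their group means had correlations of 0.22, 0.37 and 0.37. Results were also computed with the number as a block. In the tissue fits this block also ties each tumor to the glands of its number, although the labels give no such link. Deviations of equally numbered tumors and transgenic glands had correlations of -0.17, 0.33 and -0.095. Other settings were no scaling, quantile and median scaling, other floors, filters and variance models, every probe set on its own, other sets of arrays in the fit, a 2-fold minimum and leaving out each array. Added after the data were seen were the Gapdh ratio as a covariate, fits within arrays of a ratio over 2, fits without the transgenic arrays high in muscle markers, a block in a fit of the gland groups alone, and the estimated correlation under the other settings for the lists that passed with it.

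The tests were checked on simulated data with 200 changed genes. With the spread of the tissue fit, 16% of 2-fold and 83% of 4-fold changes were recovered, with 3 false among 102 calls. With that of the lines fit, 6% and 70% were recovered, with 5 false among 81 calls. No list without simulated changes was called.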

Results

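The series measured RNA in mammary tissue and in breast cancer cell lines of WAP-SVT/t mice on 12 single-color arrays. In these mice the promoter of the milk protein gene Wap directs the simian virus 40 T and t antigens to mammary epithelial cells, per the labels. Large T antigen is known to bind the p53 and RB proteins. The 9 tissue arrays held 3 lactating glands of NMRI mice without the transgene, 3 lactating glands of WAP-SVT/t mice and 3 WAP-SVT/t tumors. All 6 glands were taken at the start of lactation. The 3 other arrays held the lines ME-A, ME-B and ME-B-T/t, with 1 array each. The labels call ME-B a revertant and ME-B-T/t retransformed. Values below are array signals in intensity units after scaling, as mean ± SD over n = 3 arrays, and log2 differences ± standard error. Precision is limited by the number of arrays per group. The labels show no more than sample numbers and tumor names about separate mice, so each p value measures the spread between these samples. Every gene named as higher or lower in a replicated comparison had all 3 arrays of one group above all 3 of the other.

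The arrays differed in RNA quality and in tissue mixture. The ratio of the 3-prime to the 5-prime Gapdh control signal was 12.9, 2.28 and 40.3 in NMRI glands 1 to 3. It was 10.7, 2.49 and 22.5 in transgenic glands 1 to 3 and 5.63, 0.982 and 0.969 in tumors 1 to 3. In the lines it lay between 0.753 and 0.949. Skeletal muscle markers had mean log2 signals of 9.07 and 9.57 in NMRI glands 2 and 3 and more in NMRI gland 1. They stood at 6.62 and 6.77 in transgenic glands 1 and 2 and at 9.84 in transgenic gland 3. Tumor 1 had 9.20, against 6.25 in tumor 2 and 6.13 in tumor 3. Adipocyte markers lay between 10.2 and 10.7 in all 6 glands, at 9.24 in tumor 1, and at 7.30 and 7.40 in tumors 2 and 3.

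Transgenic glands were compared with NMRI glands to show how the glands differed at the same day of lactation. Genes of cell division were far higher in the transgenic glands. Mki67, a marker of proliferating cells, was 25.0-fold higher, with 3489 ± 489 in transgenic and 185 ± 173 in NMRI glands (adjusted p = 0.000207). Top2a, the topoisomerase that untangles chromosomes, was 19.5-fold higher (2125 ± 483 against 108 ± 11.5). Milk genes fell instead, and so did some acute phase genes, among them Saa2, which encodes a serum amyloid A protein and was 86.7-fold lower, from 7002 ± 421 to 74.1 ± 73.8.

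Among G1/S and DNA replication genes, 39 of 47 tested members rose and none fell (43 adjusted over the list alone). Their median log2 difference was 2.26. Mcm5, a subunit of the replicative helicase, was 18.6-fold higher and Uhrf1, which maintains DNA methylation, 15.4-fold higher. Gmnn, the replication licensing inhibitor geminin, was 12.3-fold higher, and Rpa2, a single-stranded DNA binding subunit, 9.79-fold higher. Of 51 G2/M and chromosome segregation genes, 48 rose, the same number as adjusted over the list alone, with a median of 2.99. The kinesins Kif2c and Kif23, at the floor in all NMRI glands, were at least 11.3-fold higher and at least 11.5-fold higher. Cdc20, an activator of the anaphase-promoting complex, was 17.8-fold higher, the chromatin protein gene Hmgb2 18.0-fold higher and Birc5, or survivin, 15.8-fold higher. Both lists passed the list test (adjusted p = 1.26e-36 and 5.78e-49), also with an estimated correlation (adjusted p = 0.0374 for each). That second pass was lost with the replicate number as a block (adjusted p = 0.0570 for each), and held in 8 of 13 other settings for G1/S and 7 for G2/M, and in 3 of 9 fits without 1 array for each.

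Of 28 DNA repair and damage checkpoint genes, 13 rose (16 adjusted over the list alone). They included Brca1, which acts in homologous recombination, at least 11.4-fold higher, Rad54l, at least 7.56-fold higher, and Rad51ap1, 7.52-fold higher. The list passed at adjusted p = 1.73e-09, but had adjusted p = 0.125 with an estimated correlation. In the RB and cyclin-dependent kinase pathway, 6 of 22 members rose (7 adjusted over the list alone). Rbl1, the RB relative p107, was 5.59-fold higher, Tfdp1, a partner of E2F factors, 3.38-fold higher and the kinase gene Cdk2 3.11-fold higher. Rbl1 is also in the G1/S list. That list passed at adjusted p = 0.00137, with adjusted p = 0.171 with an estimated correlation. Rb1 itself had 1303 ± 233 against 1522 ± 575 and did not pass (adjusted p = 0.751).

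**Figure D1:**
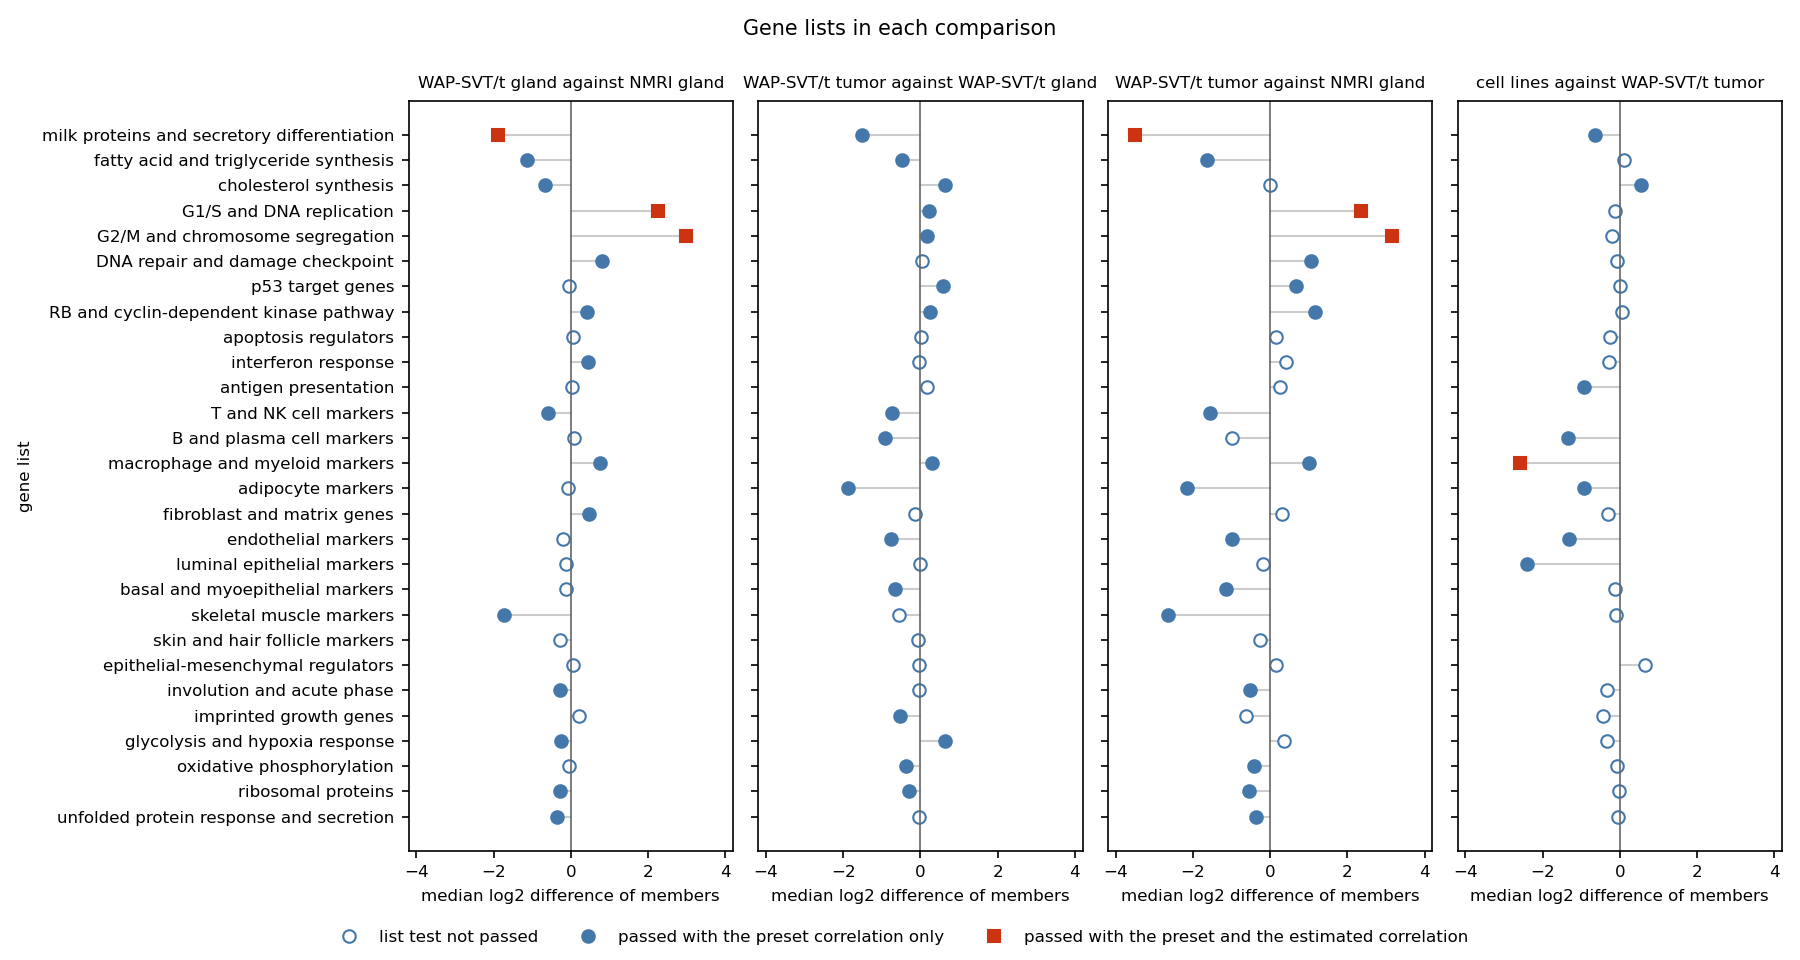
Median log2 difference of each gene list (horizontal axis, 1 row per list) in the 4 comparisons of replicated groups (panels). Open circles mark lists that did not pass the list test, filled circles lists that passed with the preset correlation only, and red squares lists that passed with both settings, such as G2/M genes at a median of 2.99 in transgenic against NMRI glands.

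Many milk genes and some lipid genes were lower in the transgenic glands, the lipid lists passing with the preset correlation only. Of 23 genes of milk proteins and secretory differentiation, 13 fell (16 adjusted over the list alone) and none rose, with a median log2 difference of -1.89. Cel, a lipase secreted into milk, was 67.6-fold lower, the casein gene Csn1s2b 37.8-fold lower and Pigr, the receptor that carries polymeric antibodies across epithelia, 8.62-fold lower. Wap fell 5.02-fold, from 15974 ± 1022 to 3702 ± 2429 (adjusted p = 0.00346). The list passed the test (adjusted p = 8.33e-14) and narrowly with an estimated correlation (adjusted p = 0.0493). With the latter it passed in 4 of 13 other settings (adjusted p from 0.0273 to 0.251) and in 2 of 9 fits without 1 array. Lao1, an L-amino acid oxidase gene outside the lists, was 62.3-fold lower. Of 23 fatty acid and triglyceride synthesis genes, 9 fell (15 adjusted over the list alone). Olah, which releases medium-chain fatty acids from their synthase, was 30.8-fold lower, and the desaturase gene Fads1 3.56-fold lower, and the malic enzyme gene Me1 had a log2 difference of -2.07 ± 0.26. Cholesterol synthesis had a median of -0.67, with 2 of 16 members lower (also 2 adjusted over the list alone), Msmo1 4.66-fold lower and Mvd 3.94-fold lower. These lipid lists passed at adjusted p = 8.51e-09 and 0.00907, and had adjusted p = 0.129 and 0.568 with an estimated correlation.

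Some secretory pathway and acute phase genes were also lower, and their lists passed with the preset correlation only. Of 32 genes of the unfolded protein response and secretion, 5 fell (adjusted over the list alone, 7 lower and 1 higher), with Ssr4, a subunit of the translocon-associated complex, 3.38-fold lower. The transcription factor genes Xbp1 and Atf4 were 2.37-fold lower and 1.75-fold lower. Involution and acute phase genes had 5 of 29 members lower (adjusted over the list alone, 7 lower and 1 higher) and a median of -0.27. Those that fell furthest were the serum amyloid genes Saa2 and Saa1, the latter 80.6-fold lower, and Lbp, which encodes a lipopolysaccharide binding protein, was 3.94-fold lower. In glycolysis and hypoxia response, 4 of 24 members fell (adjusted over the list alone, 5 lower and 1 higher), with a median of -0.26. They included the glucose transporter gene Slc2a1, 3.09-fold lower, the kinase gene Pdk1, 2.74-fold lower, and Pfkm, the muscle form of phosphofructokinase, 1.96-fold lower. Ribosomal protein genes had a median of -0.28, with Rps14 lower (1.57-fold) and no other of 42 past the threshold. Adjusted p was 0.00198 for the unfolded protein response, 0.0182 for involution, 0.0329 for glycolysis and 0.000230 for ribosomal proteins. In the same order, adjusted p = 0.526, 0.668, 0.526 and 0.512 with an estimated correlation.

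Markers of other cell types moved both ways. Macrophage and myeloid markers had a median of 0.76, with 3 of 31 higher (6 adjusted over the list alone). These were Aif1, 3.06-fold higher, Mpeg1, 2.54-fold higher, and the complement gene C1qb, 2.32-fold higher. Fibroblast and matrix genes had a median of 0.48, with Pdgfrb 2.31-fold higher and Vim 1.79-fold higher among 44 members (1 adjusted over the list alone). Interferon response genes had a median of 0.46, with 3 higher and 1 lower of 34, the same counts as adjusted over the list alone. Ifit2 was 3.58-fold higher and Oasl2 3.98-fold higher, whereas Isg20 was 3.73-fold lower. T and NK cell markers had 3 of 7 members lower, as when adjusted over the list alone, including the granzyme genes Gzma, 3.49-fold lower, and Gzmb, 3.20-fold lower, and Il2rb, 2.64-fold lower. Skeletal muscle markers had a median of -1.74 with none of 23 past the threshold, beside the low muscle signals of transgenic glands 1 and 2 given above. Over other settings and fits without 1 array this muscle median ranged from -3.19 to -1.18. Adjusted p was 0.000184, 0.00399, 0.0280, 0.0329 and 3.26e-05 for these lists in turn. The values were, in that order, adjusted p = 0.521, 0.668, 0.668, 0.512 and 0.568 with an estimated correlation.

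The 12 other lists did not pass. Medians were -0.05 for p53 target genes, 0.06 for apoptosis regulators, 0.03 for antigen presentation, 0.09 for B and plasma cells, -0.08 for adipocytes and -0.21 for endothelium. They were -0.11 for luminal epithelium, -0.11 for basal and myoepithelial cells, -0.28 for skin and hair follicle, 0.07 for epithelial-mesenchymal regulators, 0.20 for imprinted growth genes and -0.05 for oxidative phosphorylation. For the p53, antigen presentation, B cell and basal lists, the median, the mean and the test did not all have the same sign. Among p53 targets, Ckap2 was 5.66-fold higher, Apaf1, the scaffold of the apoptosome, 1.86-fold higher and Ercc5, a DNA repair nuclease gene, 1.75-fold lower. Among apoptosis regulators, Casp8ap2 was 3.59-fold higher and Birc2 2.36-fold higher. The luminal genes Muc1, Spint1 and Crb3 were 5.84-fold lower, 2.33-fold lower and 2.01-fold lower, while the keratin gene Krt18 had 5263 ± 1499 against 6129 ± 2580.3 (adjusted p = 0.820). Cdkn2a was at the floor in both groups.

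In the test behind these statements, 801 of 7899 genes changed, 481 higher and 320 lower, and 421 of the former and 267 of the latter did so by 2-fold or more. The groups did not overlap in 2454 genes (31.1%), where chance gives 10%. Without NMRI gland 1 or 2, 394 and 429 genes passed. The H2-D1 probe set chosen for the gene was 44.6-fold lower, but of 7 H2-D1 probe sets tested on their own 3 were higher and 3 lower, so no direction is given for this class I histocompatibility gene. The cholesterol, interferon, T and NK cell, fibroblast, involution, glycolysis, ribosomal and unfolded protein response lists no longer passed under at least 1 other setting or without 1 array.

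**Figure D2:**
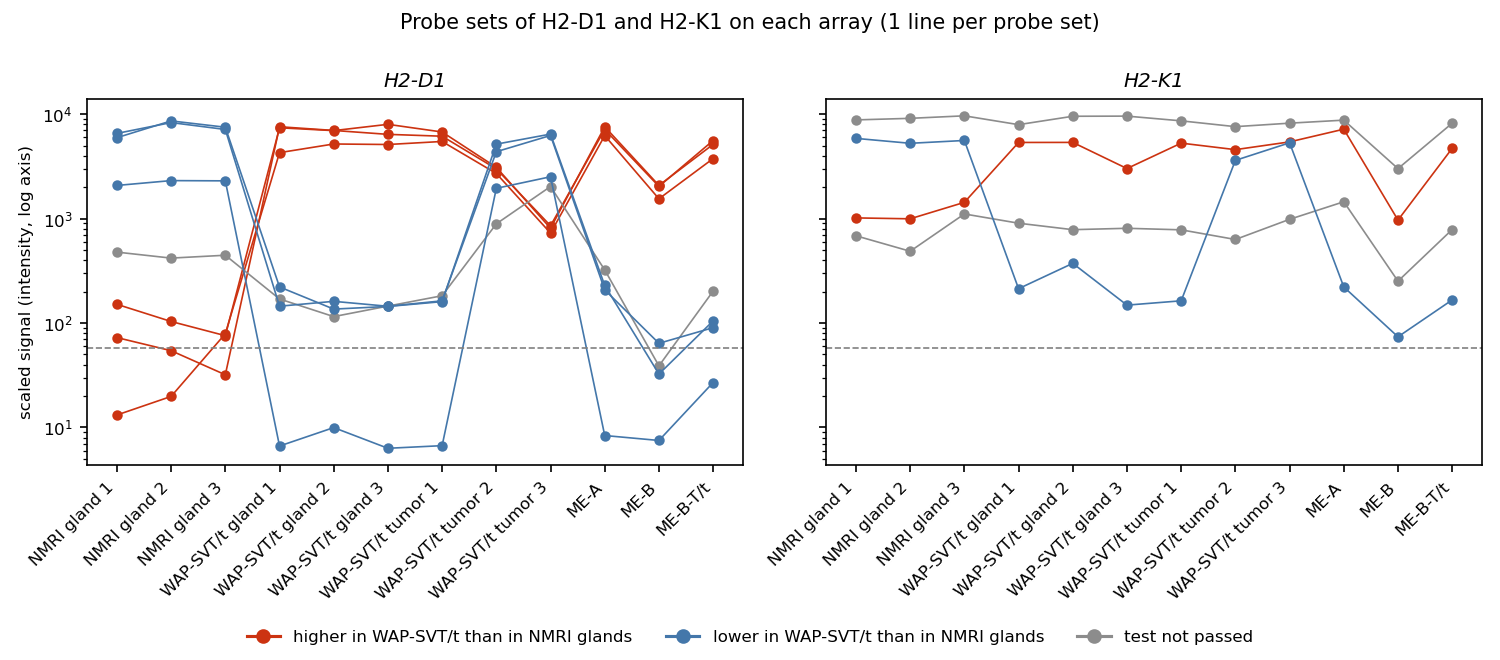
Signal of each tested probe set of H2-D1 and H2-K1 (vertical axis, log scale, intensity units) on the 12 arrays (horizontal axis), each line joining the values of 1 probe set and colored by its call between transgenic and NMRI glands. Of the H2-D1 probe sets, 3 are high in NMRI glands and 3 others in transgenic glands, and tumors 2 and 3 have signal on both.

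**Figure D3:**
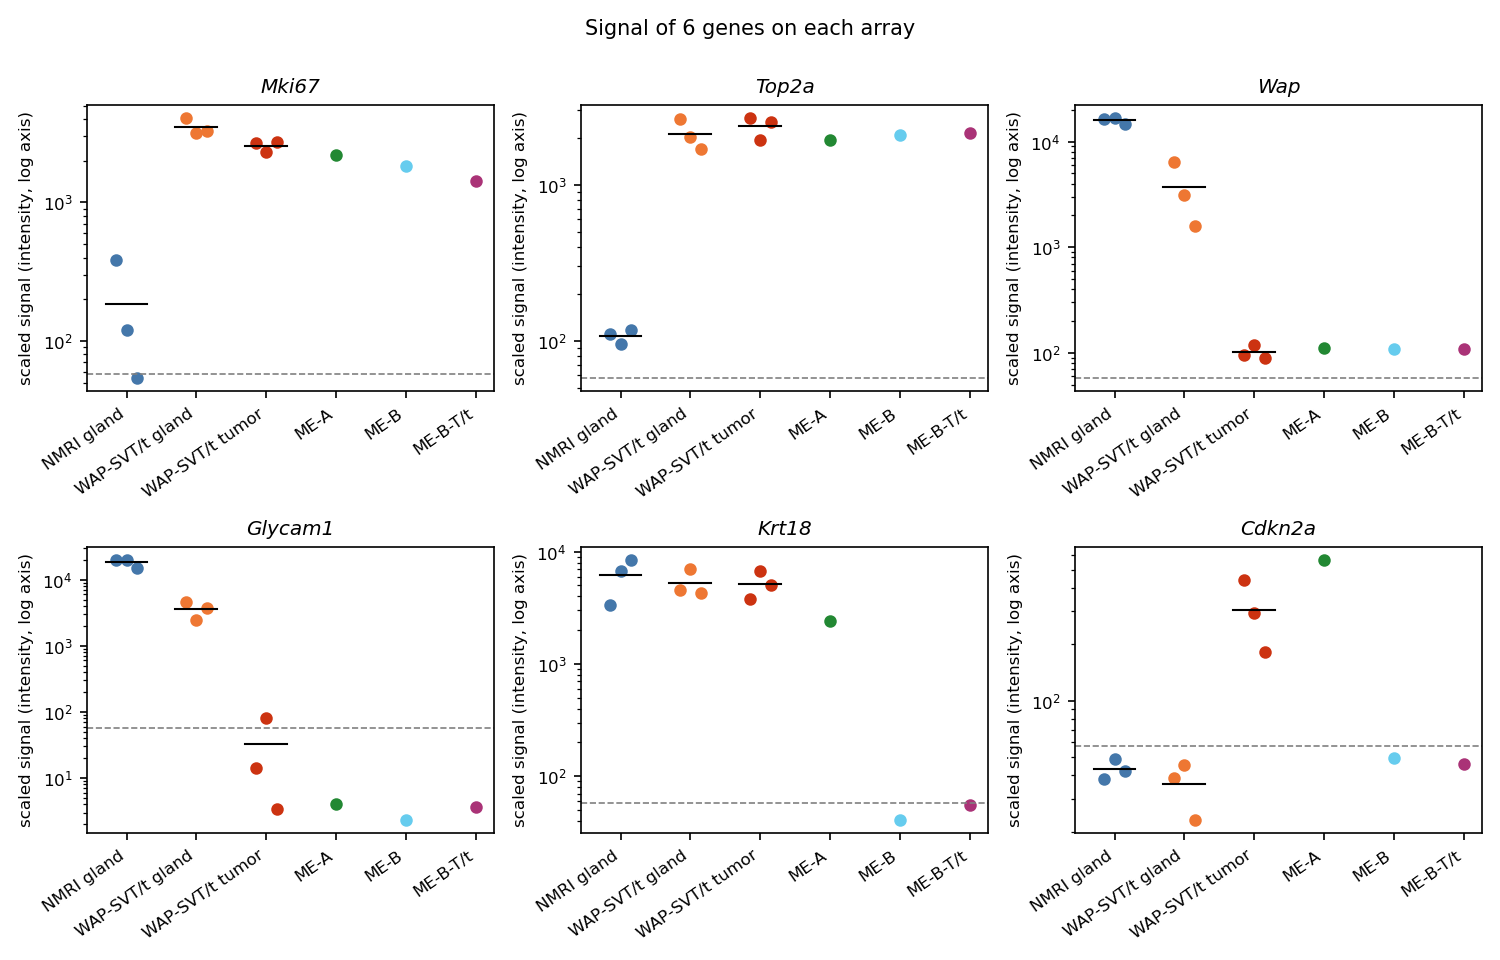
Signal of 6 genes on every array (vertical axis, log scale, intensity units), by tissue group and cell line, with horizontal bars for the group means and a dashed line for the floor of 57.4. Mki67 stood at 185 ± 173 in NMRI glands and at 3489 ± 489 in transgenic glands, and Wap at 15974 ± 1022 in NMRI glands and 102 ± 15.2 in tumors.

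Tumors were compared with transgenic glands to show what set the tumors apart from lactating tissue that carries the same transgene. Many milk, adipocyte and basal cell genes were lower in the tumors, in lists that passed with the preset correlation only, as did all lists called in this comparison. Glycam1, a mucin-like protein gene of lactating epithelium, was 53.8-fold lower (33.1 ± 42.5 against 3599.6 ± 1118, adjusted p = 2.68e-06), and Wap 31.4-fold lower. The genes with the largest rises were Tesc, which encodes the calcium binding protein tescalcin, at least 21.3-fold higher (1338 ± 689 against 11.2 ± 7.89), the collagen gene Col11a1, 14.4-fold higher, and the Notch target gene Hey1, 11.3-fold higher. The water channel gene Aqp5 was 10.6-fold higher, Prom1, or CD133, 9.32-fold higher and the phospholipase gene Pla2g7 8.17-fold higher.

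Of 23 milk genes, 11 fell (15 adjusted over the list alone), with a median of -1.52. The casein gene Csn1s2a was 47.8-fold lower and Plin2, a coat protein gene of milk fat droplets, 5.30-fold lower. The list had adjusted p = 1.53e-18, and adjusted p = 0.0660 with an estimated correlation. Fatty acid synthesis had 2 of 23 members lower, Fabp3 20.5-fold lower and Gpam 3.28-fold lower (adjusted over the list alone, 6 lower and 2 higher). Of 18 adipocyte markers, 11 fell (15 adjusted over the list alone), with a median of -1.88. The hormone gene Adipoq was 30.4-fold lower, Cidec 8.70-fold lower and Retn, or resistin, 7.74-fold lower, and the fatty acid transporter gene Cd36 had a log2 difference of -4.52 ± 0.70. The adipocyte signal was highest in tumor 1, the tumor with a Gapdh ratio of 5.63. Adjusted p was 0.0159 and 1.09e-13 for these lists, and adjusted p = 0.466 and 0.166 with an estimated correlation.

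Basal and myoepithelial markers had 7 of 17 members lower, as when adjusted over the list alone, and a median of -0.67. The keratin genes Krt5 and Krt14 were 7.31-fold lower and 8.93-fold lower, and the smooth muscle myosin gene Myh11 7.74-fold lower. Endothelial markers had a median of -0.77, with Tek, an angiopoietin receptor, 2.65-fold lower, the only one of 21 past the threshold (8 adjusted over the list alone). B and plasma cell markers had a median of -0.91, with Blnk 3.33-fold lower (3 adjusted over the list alone). T and NK cell markers had a median of -0.74 and none past the threshold (1 adjusted over the list alone). Imprinted growth genes had a median of -0.53, with Nnat 4.34-fold lower (3 adjusted over the list alone). Adjusted p was 5.70e-07, 2.47e-05, 0.00798, 0.0401 and 0.00798 in turn. In the same order, adjusted p = 0.166, 0.244, 0.466, 0.434 and 0.434 with an estimated correlation.

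Some genes of glycolysis and hypoxia response were higher in the tumors, and the list passed with the preset correlation only (adjusted p = 0.174 with an estimated correlation). It had a median of 0.64 and 3 of 24 past the threshold (adjusted over the list alone, 12 higher and 1 lower). The glucose transporter gene Slc2a1 was 3.35-fold higher, the collagen hydroxylase gene P4ha1 2.44-fold higher and the glycolytic enzyme gene Tpi1 2.43-fold higher. Of 24 p53 target genes, 3 rose, the same number as adjusted over the list alone. They were Cdkn1a, the cell cycle inhibitor p21, 7.02-fold higher, the receptor gene Epha2, 5.93-fold higher, and Psrc1, 5.11-fold higher. In the RB pathway, Cdkn1a and Cdkn2a rose (2 adjusted over the list alone), and the median was 0.26. Cdkn2a, which encodes the inhibitor p16 and the p53 regulator p19ARF, was at least 4.98-fold higher (305 ± 129.6 against 35.7 ± 11.5, adjusted p = 0.00475). Adjusted p was 5.46e-07, 0.000180 and 0.0473, and adjusted p = 0.174, 0.363 and 0.434 with an estimated correlation.

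A further 6 lists passed with no member past the threshold, also adjusted over the list alone. Medians were 0.63 for cholesterol synthesis, 0.23 for G1/S, 0.16 for G2/M, 0.29 for macrophages, -0.38 for oxidative phosphorylation and -0.29 for ribosomal proteins, the last turning to 0.03 after quantile normalization. Their adjusted p was 0.000388, 0.0218, 0.0421, 0.0421, 3.41e-06 and 9.29e-06 in turn. The values were, in that order, adjusted p = 0.434, 0.682, 0.756, 0.756, 0.434 and 0.390 with an estimated correlation. Mki67 had 2559 ± 226 in tumors and 3489 ± 489 in transgenic glands and did not pass (adjusted p = 0.724). Fibroblast and matrix genes did not pass as a list, with 3 members higher and 1 lower of 44, and, adjusted over the list alone, 6 higher and 7 lower. Those that rose were Vcan, a proteoglycan gene, 4.10-fold higher, Mgp, a matrix protein gene, 3.79-fold higher, and Thbs1, or thrombospondin, 4.63-fold higher. Of the lists that did not pass, the apoptosis, interferon, luminal, skin, epithelial-mesenchymal and unfolded protein response lists had a median and a mean of opposite sign.

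By limma, 233 of 7899 genes changed between tumors and transgenic glands, 98 higher and 135 lower. The groups did not overlap in 1550 genes (19.6%), where chance gives 10%. This count moved with the arrays and the settings: 69 genes passed without tumor 2, 71 with no filter on dim probe sets, 101 with the Gapdh ratio as a covariate, 111 without transgenic gland 1, 124 with only the compared groups in the fit, 125 without transgenic gland 3, 131 with all 12 arrays, and 24 within the arrays whose Gapdh ratio was over 2, which keep tumor 1 only, assumed to vary like the glands. The lists of fatty acid synthesis, G1/S, G2/M, the RB pathway, T and NK cells, B cells, macrophages, imprinted genes and ribosomal proteins no longer passed under at least 1 other setting or without 1 array.

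Tumors were also compared with NMRI glands, which sets tumor against normal lactating tissue. Nearly all milk genes were lower and nearly all cell division genes higher in the tumors. Glycam1 was 279-fold lower (33.1 ± 42.5 against 18174 ± 2560.2, adjusted p = 6.35e-08) and Wap 158-fold lower. Top2a was 22.0-fold higher (2384 ± 393 against 108 ± 11.5, adjusted p = 1.45e-06), and Mki67 18.4-fold higher. Ecrg4, outside the lists, was 18.5-fold higher.

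Of 23 milk genes 22 fell, the same number as adjusted over the list alone, with a median of -3.51. Csn1s2b, at the floor in all tumors, was at least 188-fold lower, and Cel was 100.1-fold lower. Saa1, of the acute phase list and also at the floor in all tumors, was at least 190.2-fold lower. G1/S genes had 44 of 47 higher (also 44 adjusted over the list alone), with Uhrf1 18.2-fold higher and the helicase gene Mcm3 14.0-fold higher. G2/M genes had 48 of 51 higher (also 48 adjusted over the list alone), with the ubiquitin conjugating enzyme gene Ube2c 20.7-fold higher and the cyclin gene Ccnb2 at least 17.9-fold higher. Medians were 2.35 and 3.14. These lists passed with the preset correlation (adjusted p = 4.47e-21, 1.50e-29 and 6.27e-37) and with an estimated correlation (adjusted p = 0.0426 for each). With the latter the milk, G1/S and G2/M lists passed in 9, 7 and 6 of 13 other settings (adjusted p from 0.0144 to 0.132), and in 3, 1 and 2 of 9 fits without 1 array.

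DNA repair genes rose in 16 of 28 members, as when adjusted over the list alone, with Brca1 at least 11.8-fold higher. The RB pathway had 12 of 22 higher (adjusted over the list alone, 12 higher and 1 lower), among them Rbl1, 4.74-fold higher, and the cyclin gene Ccne2, at least 4.48-fold higher. Cdkn2a was at least 4.98-fold higher, whereas Rb1 had 835 ± 103 against 1522 ± 575 and did not pass (adjusted p = 0.0613). Of 24 p53 targets 8 rose and 2 fell (adjusted over the list alone, 10 and 2), with Ckap2 8.48-fold higher and Gtse1, a G2 and S phase protein gene, at least 3.40-fold higher. Macrophage markers rose in 16 of 31 members and fell in 1 (adjusted over the list alone, 21 and 1), with the complement genes C1qc and C1qb 3.19-fold higher and 3.45-fold higher. Adjusted p was 1.44e-08, 0.000167, 0.0227 and 2.17e-05 in turn. In the same order, adjusted p = 0.112, 0.112, 0.464 and 0.386 with an estimated correlation.

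Fatty acid synthesis genes fell in 15 of 23 members and rose in 1 (adjusted over the list alone, 17 and 1), with Fabp3 119-fold lower and Olah, at the floor in all tumors, at least 55.5-fold lower. Adipocyte markers fell in 15 of 18 members (16 adjusted over the list alone), with Cd36 37.8-fold lower, beside the adipocyte signals given above. Basal markers had 10 of 17 lower and 1 higher (adjusted over the list alone, 10 and 2), with Krt5 7.18-fold lower and the smooth muscle actin gene Acta2 3.67-fold lower. Endothelial markers had 8 of 21 lower and 1 higher (adjusted over the list alone, 11 and 1), with the addressin gene Madcam1 4.29-fold lower. T and NK cell markers had 4 of 7 lower, as when adjusted over the list alone, with Gzma 7.32-fold lower. Skeletal muscle markers had 6 of 23 lower (13 adjusted over the list alone), with the muscle enolase gene Eno3 6.24-fold lower, beside muscle signals that among the tumors were low in tumors 2 and 3 only. Adjusted p was 1.44e-08, 2.68e-08, 0.000223, 0.000168, 0.00562 and 2.37e-05 in turn. The values were, in that order, adjusted p = 0.112, 0.165, 0.165, 0.187, 0.257 and 0.509 with an estimated correlation.

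Ribosomal protein genes fell in 24 of 42 members (adjusted over the list alone, 30 lower and 1 higher), but their median of -0.55 turned to 0.08 after quantile normalization. Oxidative phosphorylation genes fell in 11 of 46 members (10 adjusted over the list alone), with the complex I subunit gene Ndufa1 2.56-fold lower and the cytochrome oxidase gene Cox4i1 1.70-fold lower. Involution and acute phase genes fell in 10 of 29 (adjusted over the list alone, 12 lower and 1 higher), with Lbp 3.06-fold lower. Unfolded protein response genes fell in 5 of 32 (4 adjusted over the list alone), with Ssr4 3.31-fold lower. Adjusted p was 1.75e-08, 0.000117, 0.00253 and 0.0227 in turn. In the same order, adjusted p = 0.165, 0.464, 0.509 and 0.514 with an estimated correlation. Lists that did not pass still held changed genes: Dsp, or desmoplakin, was 3.16-fold higher, Elf5, a transcription factor gene of alveolar cells, 3.81-fold lower, the fibroblast gene Mgp 6.35-fold higher and the glycolytic gene Pfkp 4.82-fold higher. Cholesterol synthesis, which did not pass, had a median just under 0 and a mean above 0.

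In total 1949 of 7899 genes changed between tumors and NMRI glands, 1021 higher and 928 lower, and 863 and 655 did so by 2-fold or more. The groups did not overlap in 3469 genes (43.9%), where chance gives 10%. Without NMRI gland 1, 1227 genes passed, and 723 within the arrays whose Gapdh ratio was over 2. These keep tumor 1 as the lone tumor, which is assumed to vary like the glands, so this value also reflects the smaller group. The p53 target, skeletal muscle, involution, oxidative phosphorylation, ribosomal and unfolded protein response lists no longer passed under at least 1 other setting or without 1 array.

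The calls of both transgenic tissues against NMRI glands were then set side by side, which asks how many tumor differences were also seen in transgenic glands. Of the genes called, 423 were higher and 267 lower in both comparisons. Mki67, Top2a, Mcm5, Uhrf1 and Brca1 were among those higher in both, and Saa1, Saa2, Cel, Lao1 and Wap among those lower in both. Of the genes higher in transgenic glands, 87.9% were also higher in tumors, and of those lower, 83.4% were also lower. Of the genes higher in tumors, 41.4% were also higher in transgenic glands, and of those lower, 28.8%. Independent lists of these sizes would share 62.2 and 37.6 genes. Both comparisons use the same NMRI arrays, which by itself correlates their log2 differences: the correlation over genes was 0.78, and on average 0.50 in 100 simulations of unchanged groups with shared controls. These simulations drew every array independently and leave out the correlation between equally numbered glands. Of 598 genes called higher in tumors only, 84 also passed tumor against transgenic gland, and of 660 called lower in tumors only, 92. For the rest the difference between the tissues was not shown. Sncg, the gene of gamma-synuclein, was the 1 gene called in opposite directions, higher in transgenic glands by 1.22 and lower in tumors (-2.15), both as log2 differences. It was singled out after its values were seen. Without NMRI gland 1 or 2, 364 and 396 genes were shared.

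The cell lines were compared with the tumors as 3 cultured samples of 1 class, so the spread includes differences between the lines. By name ME-B-T/t is related to ME-B: their arrays had a rank correlation of 0.941, against 0.886 and 0.868 with ME-A. The test counts these related lines as independent samples, so its p values may be too small. Macrophage genes were far lower in the lines. Lyz1, a lysozyme gene, was at least 74.3-fold lower (2.53 ± 0.847 against 4322 ± 841, adjusted p = 7.21e-05), the protease gene Ctss at least 67.8-fold lower and the lipoprotein gene Apoe at least 67.7-fold lower. Lyz1 is outside the macrophage list. Its fall is that of the probe set used: another Lyz1 probe set had means of 65.4 in tumors and 55.5 in the lines, near the floor. Of 31 macrophage and myeloid markers 24 fell (28 adjusted over the list alone), with a median of -2.58. The genes with the largest rises were Ankrd1, with a log2 difference of 4.32 ± 0.49 (1796 ± 1154 against 75.5 ± 30.6, adjusted p = 0.00660), Cdh2, or N-cadherin, 9.98-fold higher, and the transcription factor gene Pax3, at least 8.13-fold higher.

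The macrophage list passed (adjusted p = 1.46e-37), also with an estimated correlation (adjusted p = 0.00323), which was lost without any 1 of the tumors (0.203, 0.229 and 0.174 without tumors 1, 2 and 3). The complement genes C1qc and C1qb were at least 29.5-fold lower and 21.2-fold lower, and the oxidase subunit gene Cyba at least 33.5-fold lower. Of 9 antigen presentation genes 3 fell (4 adjusted over the list alone), all of the class II pathway: H2-Aa 34.9-fold lower, Cd74 18.4-fold lower and H2-Ab1 at least 16.3-fold lower. Endothelial markers had 5 of 14 lower and 1 higher (adjusted over the list alone, 8 and 2), with Sox18 at least 3.69-fold lower, Plvap 4.22-fold lower and the endothelin gene Edn1 at least 7.27-fold higher. B cell markers had a median of -1.34 with Cd72 3.87-fold lower (3 adjusted over the list alone). Adjusted p was 0.00249, 0.00476 and 0.0346, and adjusted p = 0.852 with an estimated correlation for each of these lists. Luminal epithelial markers had a median of -2.40 with none of 25 past the threshold: Epcam had 1776 ± 3057 in the lines, where only ME-A was high, and 5939 ± 65.8 in tumors. Milk genes had a median of -0.65, adipocyte markers -0.92 and cholesterol synthesis 0.55, each with no member past the threshold. Adjusted over the list alone, 1 milk gene, 5 adipocyte markers and no luminal or cholesterol gene passed. Adjusted p was 0.000457, 0.00612, 0.00476 and 0.00237 for these lists, with adjusted p = 0.852 with an estimated correlation for each.

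Fibroblast and matrix genes did not pass as a list, with 8 of 42 lower (adjusted over the list alone, 10 lower and 4 higher), including the collagen gene Col1a2, 21.4-fold lower, and Lox, a collagen cross-linking enzyme gene, 7.78-fold lower. Tgfbi was at least 22.3-fold lower and Tgfb2, a growth factor gene, 4.62-fold higher. The mRNA binding protein gene Igf2bp3 was 7.93-fold higher and Glipr1 6.69-fold higher. Mki67 had 1817 ± 396 in the lines and 2559 ± 226 in tumors and did not pass (adjusted p = 0.293). For the fatty acid and skeletal muscle lists, which did not pass, the median, the mean and the test did not all have the same sign. In the test 169 of 7344 genes changed, 31 higher and 138 lower, and 1725 genes (23.5%) had no overlap between groups, where chance gives 10%. By limma this count fell to 0 without tumor 1 (729 genes at an unadjusted p under 0.05), 1 without tumor 2 and 3 without tumor 3, and was 779 without ME-A, 61 without ME-B and 85 without ME-B-T/t. The milk, antigen presentation, B cell, adipocyte and endothelial lists no longer passed under at least 1 other setting or without 1 array.

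The revertant line ME-B was compared with ME-A and with ME-B-T/t, which asks what set the revertant apart from both. There were no replicates, so these are values with no test. Interferon response genes were lower in ME-B: 30 of 33 members had a lower signal than in both other lines, and 17 were lower than in both by 4-fold or more. Irf7, a transcription factor gene of the interferon response, had 143 in ME-B, 2635 in ME-A and 1743 in ME-B-T/t. Usp18 had 87.2 against 1277 and 1560.3, and Psmb9, a subunit of the immunoproteasome, 70.1 against 1593 and 970.3. Genes higher in ME-B than in both other lines included Fosl1, a component of the AP-1 factor, 6.76-fold higher or more, and Hbegf, a ligand of the EGF receptor, 6.55-fold higher or more.

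**Figure D4:**
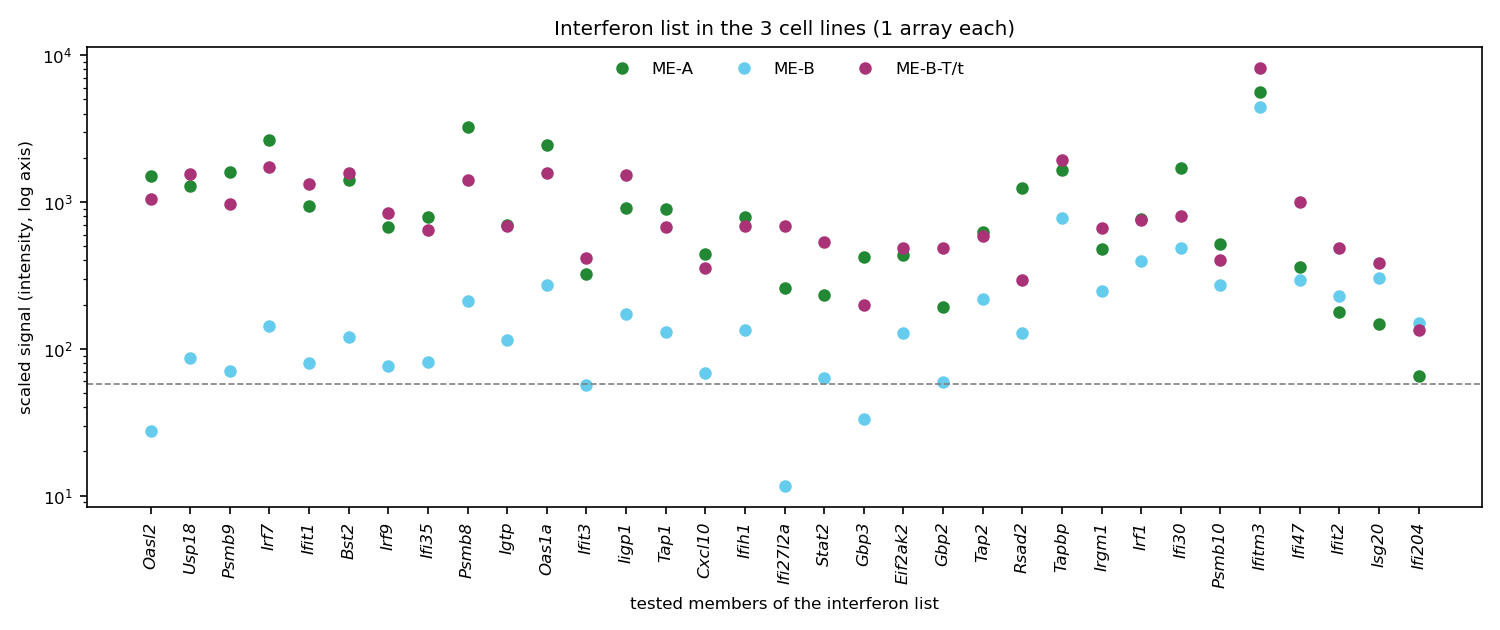
Signal of interferon response genes in the lines ME-A, ME-B and ME-B-T/t (vertical axis, log scale, intensity units, 1 array per line), with a dashed line for the floor of 57.4. Irf7 stood at 143 in ME-B and at 2635 and 1743 in ME-A and ME-B-T/t.

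The interferon list had median log2 differences of -2.49 against ME-A and -2.38 against ME-B-T/t, lower than all 10000 random lists of matched expression in both cases. The median of ME-B-T/t against ME-A was 0.16. Of 7945 genes, 49 differed by 4-fold or more from both other lines, 15 higher and 34 lower in ME-B. The lowest, given with the smaller of their differences, were Rtp4, 25.1-fold, Oasl2, at least 18.1-fold, Usp18, 14.6-fold, Psmb9, 13.8-fold, and Irf7, 12.2-fold. Next came Steap4, at least 12.1-fold, Igfbp5, which binds insulin-like growth factors, 11.97-fold, and the collagen gene Col11a1, 11.95-fold. Those higher were U90926, at least 30.2-fold, the protease inhibitor gene Serpinb2, at least 11.1-fold, Msln, or mesothelin, at least 6.45-fold, Lce1h, 6.28-fold, Eps8, 5.34-fold, and Ctla2a, at least 5.18-fold. The count of 49 was 27 with the floor at the pooled median and 78 with no floor.

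Both ME-B lines stood apart from ME-A in markers of cell type. Luminal epithelial markers had medians of -4.24 in ME-B and -4.70 in ME-B-T/t against ME-A. Of 25 members, 10 were at the floor in ME-B and 11 in ME-B-T/t, so the falls of these members are lower bounds. Krt18 had 2392 in ME-A and 40.5 in ME-B and 55.0 in ME-B-T/t, both under the floor. Fibroblast and matrix genes had medians of 3.61 in ME-B and 4.55 in ME-B-T/t, with 23 and 28 of 34 members higher by 4-fold or more. Of all 34, 13 were at the floor in ME-A. Cdkn2a had 565 in ME-A and was at the floor in both ME-B lines. Rb1 had 1035, 307 and 499, and Mki67 2209, 1825 and 1416, in ME-A, ME-B and ME-B-T/t. By 4-fold or more, 565 genes differed between ME-B and ME-A, 605 between ME-B-T/t and ME-A and 134 between ME-B and ME-B-T/t.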

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

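For the patterns below, the tests of lower H2-D1 expression, of the share of epithelial cells, of RNA integrity in the milk genes, of the scaling and RNA integrity of the ME-B array and of the loss of T/t antigen synthesis were chosen after the results were seen.

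Sncg was called in opposite directions against NMRI glands in transgenic glands and in tumors, and the tested difference between tumors and transgenic glands was -3.38 on the log2 scale (adjusted p = 0.000406, lower in 3 of 3 tumors than in all transgenic glands). The 18S rRNA control probe set, which no comparison uses, had a deposited signal of 3125.3 in tumor 2 and 1911.7 in tumor 3, against 249 at most in NMRI glands.

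Single probe sets of the histocompatibility genes H2-D1 and H2-K1, which the gene comparisons do not use, had high signals in transgenic glands and low ones in NMRI glands. H2-K1 probe sets went both ways too, 1 higher, 1 lower and 2 not passing. For H2-D1 the means in transgenic glands were 6981.5, 4855.9 and 7444, against 52.9, 37.3 and 109.9 in NMRI glands, and for H2-K1 4574.7 against 1146, while the other called H2-K1 probe set had 244 in transgenic against 5567 in NMRI glands.

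The first pattern is that H2-D1 probe sets went both ways between these glands, 3 higher, 3 lower and 1 not passing. Lower H2-D1 expression in transgenic glands, if nothing else differed, allows no higher probe set. The 3 that were higher are part of the pattern itself, and argue against it only as the whole cause. Different H2 alleles in the 2 sets of animals remain open, since the pattern led to this explanation and cannot also test it. On the called H2-D1 probe sets tumor 1 and the 3 lines followed the transgenic glands, while tumors 2 and 3 had signal on both kinds. If the animals differed in genetic background, the comparisons with NMRI glands would not separate it from the transgene. The H2-D1 probe set used for the gene had 5157 and 6437 in tumors 2 and 3. It had 160 in tumor 1 and 221, 136 and 144 in transgenic glands 1 to 3. A background difference could thus also enter the comparisons of tumors with transgenic glands and of lines with tumors. A wider carried-over segment around H2-D1 was tested on 40 tested genes in GRCm38.p6, the 20 nearest on each side, leaving out H2 genes. Of these, 7 were called, where 4.06 were expected and up to 8 lay within chance. Since a segment need not change the expression of its genes, this bound leaves it open. Cross-hybridization between class I genes was not tested, and the labels call all the gland donors NMRI.

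The next pattern is the lower milk list in transgenic glands and, again, in tumors. A lower share of epithelial cells would lower luminal markers too, but the luminal list had medians of -0.11 in transgenic against NMRI glands and -0.025 in tumors against transgenic glands, and its lower quartiles of -0.54 and -0.39 lay above 0.5 times the milk medians, -0.94 and -0.76. In transgenic against NMRI glands 3 of 25 luminal members were called lower and 0 higher, with a mean of -0.29, so a partial role stays open. RNA integrity would shrink the milk medians once the Gapdh ratio is a covariate, but they stayed at -1.81 and -1.58. The NMRI and transgenic glands had similar ratios, so the covariate could move the first median little. Tumors 2 and 3, at 0.982 and 0.969, lay under every gland, so the tumor adjustment extrapolates and cannot decide on RNA integrity. The luminal values argue against a lower share of epithelial cells as the whole cause. The similar ratios argue against RNA integrity as the whole cause of the difference between the glands. A state of the epithelial cells other than secretion may account for the pattern, which remains a hypothesis, and neither the timing within the day of lactation nor the lactation state of the tumor-bearing mice was tested.

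The last pattern is the interferon list in ME-B, lower than in both other lines. Quantile normalization would remove an error in the scale of the ME-B array, but left medians of -2.42 against ME-A and -2.33 against ME-B-T/t, the latter with an upper quartile of members of -1.40, and its Gapdh ratio of 0.897 lay between those of the other lines, which argues against RNA integrity. Loss of T/t antigen synthesis could lower these genes, and predicts a higher list in transgenic than in NMRI glands. There the list had a median of 0.46 and passed as higher with the preset correlation (adjusted p = 0.0280). It did not pass with an estimated correlation (adjusted p = 0.668). With 1 array per line, loss of T/t antigen synthesis cannot be told apart from other differences between the lines. Culture conditions and cell density are not given in the sources used here and were not tested.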

How the results depend on the processing

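The tests added after the data were seen were those with the Gapdh ratio, those without transgenic gland 3 and tumor 1, the block in the gland groups alone, and the estimated correlation under other settings; the others were planned. Signal over background and 3 arrays per group limit the calls. Fits within Gapdh ratios over 2 hold tumor 1 as the lone tumor, which is assumed to vary like the glands, so they do not separate RNA quality from the smaller group. Unless stated, the cause was not tested.

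Transgenic against NMRI glands, 801 genes, stayed within 1.5-fold in all settings except without 1 array (394 without NMRI gland 1 and 429 without NMRI gland 2, up to 807). As deposited, 71.2% of its calls were higher, against 60.0%, with the median of all genes shifted by 0.10. Tumors against transgenic glands, 233 genes, gave 71 with no filter (more genes tested) and 124 with only the compared groups (fewer arrays). The count was 131 with all 12 arrays and 101 with the Gapdh covariate. It was 24 within ratios over 2, where the range of RNA quality and the number of arrays both changed. Leaving out 1 array, it ranged from 69 (without tumor 2) to 228, with 111 without transgenic gland 1 and 125 without transgenic gland 3. Tumors against NMRI glands, 1949 genes, gave 2958 with every probe set tested (more tests), 723 within ratios over 2, and 1227 (without NMRI gland 1) to 2279 leaving out 1 array. Lines against tumors, 169 genes, gave 91 with no filter, 95 with the filter at the 70th percentile, 300.0 with every probe set, 429 with all 12 arrays, 54 with the covariate and 61 without ME-B. Leaving out 1 array it gave by limma 0 without tumor 1 (729 at an unadjusted p under 0.05), 1 without tumor 2, 3 without tumor 3, 85 without ME-B-T/t and 779 without ME-A. Genes shared by both transgenic tissues, 690, numbered 364 (without NMRI gland 1) to 683, with 396 without NMRI gland 2. ME-B differed from both lines in 49 genes, 78 with no floor, 27 with the floor at the median, 288 at 2-fold and 14 at 8-fold. With the replicate block 928, 283 and 2152 genes passed in the tissue comparisons and 782 were shared; with the block in the gland groups alone, 1177. Without transgenic gland 3 and tumor 1, the counts were 728, 177 and 1891, and 650.0 were shared. The transgenic arrays kept there all had lower muscle signals than every NMRI gland. Against NMRI glands this setting therefore cannot separate muscle content from the other differences between the groups.

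Lists passing fell to 10 (tumors against transgenic glands) and 5 (lines) with the filter at the 70th percentile, to 3, 0, 3 and 1 with camera's estimated correlation (6, 5, 6 and 1 at an unadjusted p under 0.05), and in the lines ranged from 4 (without tumor 1) to 10 leaving out 1 array. With the estimated correlation, the milk, G1/S and G2/M lists that passed against NMRI glands did so in few fits without 1 array. In transgenic glands they did not pass without any 1 of the NMRI glands, transgenic gland 2 or 3 or tumor 1, nor milk without tumor 2 (adjusted p from 0.0505 to 0.141). In tumors they did not pass without any 1 of the same arrays, nor G1/S without transgenic gland 1 or tumor 3, nor G2/M without tumor 3 (0.0521 to 0.0933). None passed without transgenic gland 3 and tumor 1 together (in transgenic glands 0.178, 0.169 and 0.147; in tumors 0.1002 each) or with the covariate (0.108, 0.0916 and 0.0916; in tumors 0.0832 each). With the replicate block milk passed in both (0.0347 and 0.0166) and the others did not (0.0570 and 0.0622 each); with the block in the gland groups alone all had 0.251; within ratios over 2, G2/M in tumors had 0.108. H2-D1 turned to 6.13 with quantile normalization, 5.69 with the floor at the median and 6.14 with all 12 arrays, and ranged from -5.58 to 6.39 leaving out 1 array, because another of its probe sets was chosen. After quantile normalization the ribosomal median turned to 0.025 in tumors against transgenic glands and 0.076 against NMRI glands, and Rpl41 in the latter to 0.047. In tumors against transgenic glands the muscle median turned to 0.83 with the covariate and 1.51 within ratios over 2, ranging from -1.48 to 0.44 (without transgenic gland 3), and the fibroblast median turned to 0.37 within ratios over 2. Within these ratios the adipocyte, endothelial, imprinted and p53 target medians shrank to -1.17, -0.28, -0.099 and 0.23. Those of milk and glycolysis grew in size, to -1.63 and 0.76. In lines against tumors with no filter, the B cell median turned to 0.10, and the tested direction of the muscle list turned while its median stayed negative (-0.10 to -0.78). There, leaving out 1 array, the endothelial median ranged from -1.71 to 0.77 (without tumor 2; 0.72 without tumor 1), the fibroblast median from -1.47 to 1.01 (without ME-A) and the interferon median from -0.86 to 0.48 (without ME-B). Of 3716 values of named genes in settings other than leaving out 1 array, 3419 kept direction and side of the threshold, 236 lost it, 45 gained it, 12 moved and 4 turned; leaving out 1 array, 1845 of 2073 did so and 5 turned.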

Other observations

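The lists and the counts for other groupings of the arrays were planned, but which lists of the lines to mention was chosen after the values were seen. Besides interferon genes, other groups differed between the lines, with no replicates and no test. Cholesterol synthesis genes were lower in ME-B, with 14 of 16 members lower than in both other lines and medians of -0.76 against ME-A and -1.004 against ME-B-T/t, under all 10000 random lists. Antigen presentation genes were lower than in both other lines in all 6 members, with medians of -0.72 and -1.09. The p53 target genes had a median of 0.90 in ME-B against ME-B-T/t, above all random lists, and 0.19 against ME-A. G1/S and G2/M genes had medians of 0.26 and 0.23 against ME-B-T/t and -0.01 and 0.00 against ME-A.

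Against ME-A, both ME-B lines had lower milk genes, with medians of -1.51 in ME-B and -1.005 in ME-B-T/t, and lower involution and acute phase genes (-1.54 and -1.25). Involution genes included 5 and 5 of 29 at the floor in these lines. Epithelial-mesenchymal regulators, 6 of 22 at the floor in ME-A, were higher in both (1.75 and 1.42). By 4-fold or more, 161 genes were higher and 225 lower in both ME-B lines than in ME-A.

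For each replicated comparison the 6 arrays allow 10 splits, too few for a share under 0.05, and only 1 split, the real one, gave as many genes. Transgenic against NMRI glands gave 801 genes, tumors against transgenic glands 233 and tumors against NMRI glands 1949, and by limma the other splits gave at most 0 genes, with up to 631, 796 and 330.0 at an unadjusted p under 0.05. The splits that part all 3 gland numbers, as the real one does, were among these. Every other split mixes the real groups, so a real difference widens the spread within its groups. Few calls in the other splits therefore say little about chance. Lines against tumors gave 169 genes, and the highest other split gave 2, with ME-A in the group of tumors 2 and 3.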
